A study of Homo sapiens with 12 samples.

How the data were processed

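The counts were used as deposited. Per the authors' notes, Trim Galore, HISAT2 and StringTie were used with the GRCh38/hg38 genome, without versions. The program that counted reads, the annotation release and the strand setting were not given in the sources used here. Per the protocols in the labels, RNA was prepared with a Qiagen RNeasy kit, and libraries were made from 1 µg of total RNA with a SMARTer mRNA kit.

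The table held 24302 features in 12 libraries, 3 in each of 4 groups, and was not renormalised before testing. Of these, 19974 carried Ensembl identifiers, 19883 of them matched to a name, and 4328 were unnamed features called NewGene. 4118 features had no counts. 15 symbols occurred more than once. Coordinates are 1-based on GRCh38. Near-identical copies of a gene and genes that overlap on opposite strands are uncertain, since multiple mapping and strand were not stated.

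Genes were kept by filterByExpr with the groups (14792 tested), scaled by TMM and tested with edgeR's quasi-likelihood F test on all 4 groups, with 8 residual degrees of freedom and Benjamini-Hochberg adjustment within each comparison. Genes were called at an adjusted p under 0.05 with no minimum change. An exact test of 3 against 3 libraries cannot go below p = 0.1. A gene was counted as opposite in both mutants when it was called in WT against GFP and in each mutant against WT in the opposite direction. Where a group had no counts, a floor of 3 counts over the group (the 95% bound) gave a bound on the fold. CPM in log2 used a prior count of 2. Versions were R 4.3.3, edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0.

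30 lists of genes, the comparisons and all alternatives except those named below as added were fixed before the data were examined. The lists were the AP-2 family and partners, described AP-2 targets, ZNF genes, AP-1 and immediate early genes, interferon-stimulated genes, NF-kB genes, basal squamous genes, squamous differentiation, epithelial junctions, mesenchymal genes, genes of G1/S, of G2/M, p53 targets, apoptosis, the unfolded protein response, heat shock, hypoxia and glycolysis, YAP and TEAD targets, the TGF-beta response, Notch and Wnt genes, NRF2 and ferroptosis, cholesterol and fatty acid synthesis, neural crest genes, ribosomal proteins, ribosome biogenesis, oxidative phosphorylation, mitochondrially encoded mRNAs, replication-dependent histones, and markers of fibroblasts and of leukocytes and endothelium. Lists with at least 3 tested members were tested with limma's camera with a preset correlation of 0.01, which compares a list with the other genes. Camera with an estimated correlation (42 of 89 calls kept) and fry, which tests a list by itself, were alternatives.

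TFAP2B is named throughout, ZNF131, TFAP2A and TFAP2C against GFP. Besides these, genes are named from the 10 largest rises and 10 largest falls of each comparison, among called genes with a mean of at least 5 CPM in the higher group, libraries that do not overlap between groups and an established symbol. Up to 4 members of a list with the lowest adjusted p are named, and other called members as examples. Of the genes opposite in both mutants, genes are named from the 10 in each direction with the largest WT change. Not every gene that met these rules is named.

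Alternatives were median-ratio and upper-quartile scaling, no filter, a filter of 1 CPM in 3 libraries, DESeq2, limma-voom, only the 2 groups compared, the replicate number in the model, a minimum of 2-fold, an adjusted p under 0.01, single libraries left out and named symbols alone. Added after the data were seen were the AP-2 family list without TFAP2B, the fits without mitochondrially encoded mRNAs, upper-quartile scaling for lists and the removal of GC or length trends, with offsets over 20 bins of genes with a mean of at least 1 CPM. GC and length were those of the longest transcript of a gene. Fold changes against GFP share a control, so their correlation was compared with 20 simulations without any effect.

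The code was tested on simulated counts with known changes. edgeR called 64.2%, 89.6% and 98.5% of the genes changed 1.5, 2 and 4-fold, and 9 unchanged genes, against 33 by DESeq2 and 8 by limma-voom. Of 200 genes made opposite in both mutants, 164 were called, with 0 unchanged. With a simulated GC trend 3500 unchanged genes were called before correction and 4 after. That trend was built from the same GC values that the correction uses. It therefore checks the code and not how fully a real bias is removed. Camera called the raised list and 0 of 20 unchanged lists.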

Results

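RNA of KYSE150 cells, an established line of human esophageal squamous cell carcinoma, was sequenced in 12 libraries that form 4 groups of 3. The cells carried GFP, GFP-tagged TFAP2β of normal sequence (WT), or 1 of 2 altered forms of the tagged protein, labelled Mut_IDR3 and ΔIDR3, which the series describes as deficient in phase separation. TFAP2β, the product of TFAP2B, is a transcription factor of the AP-2 family, and an IDR is an intrinsically disordered region of a protein. ΔIDR3, where Δ is the usual sign for a deletion, is written dIDR3 here. The libraries held 30.7 M to 43.5 M counts. The group means were 35.9 ± 5.53 M for GFP, 38.7 ± 4.34 M for WT, 37.3 ± 6.18 M for Mut_IDR3 and 39.5 ± 1.68 M for dIDR3. Values after ± are SDs over 3 libraries, SE is the standard error of a log2 fold change, and CPM are counts scaled to the size of the library. The labels do not say whether the replicates were separate cultures, so the p-values measure only the spread between these samples, which may be technical. Coordinates are 1-based on GRCh38.

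TFAP2B (ENSG00000008196, chromosome 6, 50818723 to 50847613) was nearly silent in the GFP libraries and abundant in all 9 construct libraries. Its level was 0.124 ± 0.142 CPM with GFP, from 13 counts in all, 280.3 ± 45.6 CPM with WT, 702 ± 25.9 CPM with Mut_IDR3 and 704 ± 62.8 CPM with dIDR3. Both mutants therefore held more TFAP2B RNA than WT, with a log2 fold change of 1.32 (SE 0.12, adjusted p = 5.11e-07) for Mut_IDR3 and 1.33 (adjusted p = 3.07e-07) for dIDR3. The mutants differed from each other by a log2 fold change of -0.01 (adjusted p = 0.989).

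The comparison of WT with GFP asks which genes change when the unaltered protein is added. Among the largest rises of genes with at least 5 CPM in the higher group were type III interferons, which cells secrete in antiviral defence, and genes that interferon switches on. IFNL1 (chromosome 19, 39296325 to 39298673) was at 27.1 ± 3.15 CPM with WT and had no counts with GFP, which makes it at least 994-fold higher. CCL5, an inflammatory chemokine, rose 283-fold (log2 fold change 8.15, SE 0.12, adjusted p = 6.11e-16), from 2.98 ± 0.0622 to 846 ± 61.7 CPM. The epithelial keratin gene KRT15, which is typical of basal squamous cells, fell 12.2-fold (log2 fold change -3.60, SE 0.07, adjusted p = 5.41e-15), from 465 ± 10.6 to 38.2 ± 2.19 CPM. KRT14, from the same keratin cluster of chromosome 17 and also a basal gene, rose from 227 ± 2.2 to 806 ± 68.1 CPM (log2 fold change 1.83).

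Of 14792 genes tested, 8118 (54.9%) differed between WT and GFP, 4102 higher and 4016 lower with WT. A change of at least 2-fold was seen in 618 higher and 1039 lower genes. Among the other genes with large rises, IFNL2 had no counts with GFP and was at least 524-fold higher, and IFNL3 had a ratio of counts of 636 (95% counting interval 217 to 3085). The reads of IFNL2 and IFNL3 are uncertain between these near-identical copies. CXorf49, which has a near-identical copy of its own, had a ratio of 717 (128 to 28368). Such intervals and floors cover counting error only. The antiviral gene RSAD2 rose 157-fold to 322 ± 28.9 CPM, and the RNA sensor gene DHX58 rose 112-fold to 25 ± 1.37 CPM. The chemokine gene CCL3 rose by a log2 fold change of 7.14.

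LOXL4, a lysyl oxidase gene, fell 84.1-fold with WT, from 15.5 ± 1.24 to 0.191 ± 0.165 CPM (log2 fold change -6.39, SE 0.38). The lipase gene CEL fell by 3.49 on the log2 scale, and TP73, a relative of the p53 gene, fell by 2.86. MECOM, a transcription factor gene, fell from 42.1 ± 1.55 to 6.41 ± 0.826 CPM (log2 fold change -2.71). GBP6 fell by 2.62, KLK8 by 2.56, NRIP1 by 2.45 and LRG1 by 2.34 on the log2 scale.

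The relatives of TFAP2B moved too. TFAP2A rose from 59.7 ± 1.35 to 127 ± 3.75 CPM (log2 fold change 1.09, adjusted p = 4.51e-09), TFAP2C rose from 34.4 ± 1.83 to 48.1 ± 4.97 CPM (0.48, adjusted p = 0.000332), and the AP-2 coactivator gene CITED2 rose from 52.8 ± 2.35 to 148 ± 5.69 CPM (1.49). ZNF131, a zinc-finger gene, fell from 23.4 ± 0.464 to 12.8 ± 1.19 CPM (log2 fold change -0.87, adjusted p = 1.47e-06). In the list of the AP-2 family and partners, 8 of 14 members rose, 3 fell and 3 were not called, with 8 and 3 adjusted over the list alone and a median of 0.37 (adjusted p = 0.0688). TFAP2B, the gene of the constructs, is itself 1 of the 8. Without it, in a test added after seeing the data, 7 of 13 rose and 3 fell, also adjusted over the list alone (adjusted p = 0.17). Of 33 described AP-2 target genes, 18 rose, among them GATA3 (2.24), PLAU (2.83-fold) and CDH1 (1.03), 7 fell and 8 were not called, with 20 and 7 adjusted over the list alone. Their median was 0.35 (adjusted p = 0.00483), and adjusted p = 0.176 with an estimated correlation.

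**Figure D1:**
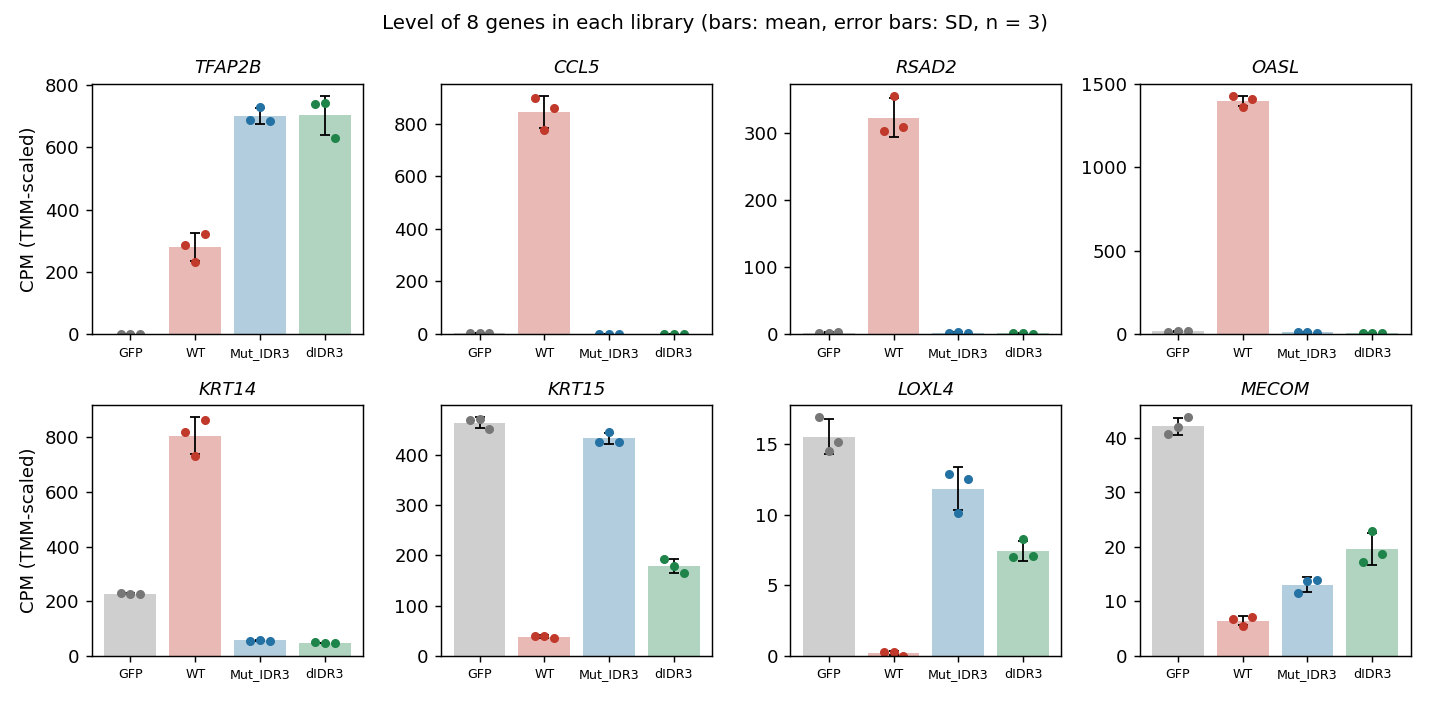
CPM of TFAP2B, CCL5, RSAD2, OASL, KRT14, KRT15, LOXL4 and MECOM in each of the 12 libraries, by group, where points are libraries, bars are means and error lines are SDs (n = 3). CCL5, RSAD2 and OASL were high in the WT libraries alone, KRT15 fell with WT from 465 to 38.2 CPM, and KRT14 was lower with both mutants than with GFP.

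Interferon-stimulated genes rose as a group with WT. Of 44 tested, 33 rose, 4 fell and 7 were not called, with 33 and 4 adjusted over the list alone, and the median log2 fold change was 1.76 (adjusted p = 6.75e-11). OASL rose from 14.7 ± 0.951 to 1397 ± 32.7 CPM, ISG15 from 35 ± 1.61 to 1237 ± 72 CPM (log2 fold change 5.14, SE 0.07) and IFIT1 from 16.3 ± 1.17 to 426 ± 40.8 CPM (4.71, SE 0.08). Genes of NF-kB signalling and inflammatory cytokines rose in 25 of 32 cases, 2 fell and 5 were not called, with 25 and 2 adjusted over the list alone and a median of 1.35 (adjusted p = 1.59e-08). They included TNFAIP3 (3.25, SE 0.15), NFKBIA (2.25, SE 0.07) and ICAM1 (1.33, SE 0.08), which are induced by NF-kB. Immediate early genes and AP-1 factors, the fast responders to growth signals and stress, rose in 32 of 34 cases, with 1 lower and 1 not called. Adjusted over the list alone the counts were 32 and 1, and the median was 1.86 (adjusted p = 1.18e-16). CYR61 rose from 301 ± 7.83 to 2061 ± 34 CPM (2.78, SE 0.04), FOSL1 from 33.7 ± 2.32 to 198 ± 13.8 CPM (2.56), and ZFP36 and IER3 rose by log2 fold changes of 2.13 and 2.01.

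Genes of the squamous epithelium went both ways with WT. Of 27 genes of its basal layer, 11 rose, 12 fell and 4 were not called, with 11 and 12 adjusted over the list alone, and the median was 0.03 (adjusted p = 0.758). KRT17 rose to 2362 ± 215 CPM (1.61). Of 34 genes of squamous differentiation, 14 rose, 9 fell and 11 were not called, with 16 and 9 adjusted over the list alone. Their median was -0.04 while the mean was 0.52 and the test leaned to higher (adjusted p = 0.434). KLF4 rose from 10.2 ± 1.6 to 86 ± 7.19 CPM (3.08), KRT16 rose by 1.74, and ELF3 fell from 108 ± 4.57 to 27.5 ± 1.48 CPM (-1.97). Epithelial junction genes rose in 19 of 29 cases, 2 fell and 8 were not called, with 21 and 2 adjusted over the list alone. CLDN4 rose from 242 ± 11.2 to 1005 ± 109 CPM. The junction median was 0.43 (adjusted p = 1.27e-05), and adjusted p = 0.117 with an estimated correlation. Mesenchymal genes rose as well, 19 of 27 with 1 lower and 7 not called, and 20 and 1 adjusted over the list alone, with a median of 0.73 (adjusted p = 2.33e-06). The matrix genes FN1 and THBS1 rose by 1.86 and 1.16.

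Genes of the G1/S transition and DNA replication were lower with WT. Of 45 tested, 24 fell, 8 rose and 13 were not called, with 24 and 8 adjusted over the list alone and a median of -0.17 (adjusted p = 0.0028). HELLS fell from 57.2 ± 3.87 to 22.5 ± 2.07 CPM (-1.34), BRCA1 fell by 1.32 and MCM6 by 0.83 on the log2 scale. Of 46 genes of G2/M and mitosis, 26 fell, among them KIF11 (-1.02), 16 rose, among them CDC20 (0.74), and 4 were not called. These counts were the same adjusted over the list alone, and the median was -0.23 (adjusted p = 0.373). Targets of p53 rose in 17 of 30 cases, 7 fell and 6 were not called, also 17 and 7 adjusted over the list alone, with a median of 0.43 (adjusted p = 0.0042). PMAIP1 rose by 2.53 and GADD45A by 1.53. Of 29 regulators of apoptosis, 13 rose, such as BCL2L1 (1.13), 9 fell and 7 were not called, and 13 and 9 adjusted over the list alone, with a median of 0.15 (adjusted p = 0.242).

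Of the stress and signalling lists, those of the unfolded protein response, hypoxia and heat shock were called with WT. Genes of the unfolded protein response and ATF4 rose in 23 of 38 cases, 5 fell and 10 were not called, with 23 and 5 adjusted over the list alone and a median of 0.39 (adjusted p = 0.000471). PPP1R15A rose by 2.34, ATF3 by 1.82 and XBP1 by 1.79. Hypoxia and glycolysis genes rose in 21 of 36 cases, such as SLC2A3 (1.86), 7 fell and 8 were not called, with 21 and 7 adjusted over the list alone. Their median was 0.31 (adjusted p = 0.0028), and adjusted p = 0.125 with an estimated correlation. Heat shock genes and chaperones rose in 14 of 23 cases, such as HSPB8 (1.03), 5 fell and 4 were not called, with 14 and 5 adjusted over the list alone and a median of 0.30 (adjusted p = 0.0263). That call had adjusted p = 0.0825 with an estimated correlation and 0.0647 without WT replicate 2. Targets of YAP and TEAD rose in 13 of 25 cases, such as CTGF (3.22), 6 fell and 6 were not called, with 13 and 6 adjusted over the list alone and a median of 0.26 (adjusted p = 0.0806). TGF-beta response genes rose in 12 of 25 cases, such as JUNB (1.15), 5 fell and 8 were not called, with 12 and 5 adjusted over the list alone and a median of 0.29 (adjusted p = 0.0551).

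Of 23 Notch and Wnt genes, 7 rose, 5 fell, such as JAG2 (-1.35) and NOTCH3 (-1.30), and 11 were not called, with 7 and 5 adjusted over the list alone. The median was -0.02 and the mean -0.09 although the test leaned to higher (adjusted p = 0.962). Of 31 genes of cholesterol and fatty acid synthesis, 11 rose, 12 fell, such as ELOVL6 (-1.23), and 8 were not called, with 11 and 12 adjusted over the list alone. The median was 0.03, the mean -0.05 and the test leaned to lower (adjusted p = 0.962). Of 33 NRF2 and ferroptosis genes, 10 rose, such as FTH1 (0.55), 11 fell, such as TFRC (-1.30), and 12 were not called, with 10 and 11 adjusted over the list alone and a median of -0.06 (adjusted p = 0.715). Neural crest and sympathetic genes rose in 6 of 7 cases, such as SOX9 (2.15), and 1 was not called, with 6 adjusted over the list alone and a median of 0.55 (adjusted p = 0.00403). This call had adjusted p = 0.0573 with an estimated correlation, and 0.0578 when genes with low counts stayed in.

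Lists of the protein-making and energy machinery went different ways. Of 82 ribosomal protein genes, 35 rose, such as RPL28 (0.65), 10 fell and 37 were not called, with 35 and 10 adjusted over the list alone and a median of 0.12 (adjusted p = 0.0178). The call had adjusted p = 0.751 with an estimated correlation, 0.0655 by fry and 0.208 without WT replicate 2. Relative to the GFP mean the list was at 0.18 and 0.20 in WT replicates 1 and 2 and at -0.04 in replicate 3, without which the median was 0.19. Of 46 genes of ribosome biogenesis, 12 rose, such as SRM (0.90), 19 fell, such as DDX18 (-1.20) and DDX21 (-1.14), and 15 were not called, with 12 and 19 adjusted over the list alone and a median of -0.03 (adjusted p = 0.141). Nuclear genes of oxidative phosphorylation rose in 34 of 79 cases, such as CYC1 (0.60), 7 fell and 38 were not called, with 34 and 7 adjusted over the list alone and a median of 0.13 (adjusted p = 0.00996). Here adjusted p = 0.712 with an estimated correlation, and 0.0967 without WT replicate 2, and WT replicates 1, 2 and 3 were at 0.19, 0.24 and -0.08. Without WT replicate 3 the median was 0.23. Of the 13 mRNAs encoded by the mitochondrial genome, 12 fell and 1 rose, also adjusted over the list alone, with a median of -0.91 (adjusted p = 1.14e-05), and adjusted p = 0.226 with an estimated correlation. MT-CO3 fell from 9812 ± 413 to 4205 ± 251 CPM. These mRNAs took 10.3 ± 0.406% of counts with GFP, 5.75 ± 0.356% with WT, 8.36 ± 0.235% with Mut_IDR3 and 7.72 ± 0.0634% with dIDR3.

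Histone genes of the replication-dependent clusters rose in 15 of 33 cases and 18 were not called, with 14 higher adjusted over the list alone. HIST1H1C rose from 29 ± 2.43 to 94.5 ± 1.68 CPM (1.70) and HIST1H2AC by 1.65. The median was 1.08 (adjusted p = 0.000495), or 0.66 without GFP replicate 2, and adjusted p = 0.0619 with an estimated correlation. Of 367 zinc-finger genes named ZNF, 152 fell, such as ZNF488 (-1.55) and ZNF664 (-0.69), 59 rose, such as ZNF697 (0.93), and 156 were not called, with 153 and 61 adjusted over the list alone. The median was -0.27 (adjusted p = 0.00483), and adjusted p = 0.226 with an estimated correlation. Markers of cell types other than squamous cells were few. Of 5 fibroblast genes, 1 rose (COL1A1, 0.85), 2 fell (C1S, -1.20, and C1R, -0.91) and 2 were not called, and the counts adjusted over the list alone were the same. The median was 0.02 while the mean was -0.09 and the test leaned to lower (adjusted p = 0.715). Of 6 leukocyte and endothelial genes, CDH5 had no counts with WT and was at least 21.6-fold lower, CD68 rose by 0.37 and 4 were not called, the same adjusted over the list alone. The median was 0.12 and the mean -1.02 (adjusted p = 0.962). The rise of CD68 was 0.09 (adjusted p = 0.228) once a trend with GC content was removed.

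The changes with WT followed the GC content of the genes. Across genes, which are not independent replicates, the Spearman correlation of GC content with the log2 fold change was 0.58 for WT against GFP, 0.51 for Mut_IDR3 and 0.24 for dIDR3. With transcript length it was -0.29, -0.22 and -0.10 in the same order. After a GC trend was removed from every library, an alternative chosen after seeing the data, 5115 (63.0%) of the 8118 genes were still called with the same sign and 220 with the opposite sign. NewGene features, 516 of the 8118, had no GC value and were left uncorrected, here and in the other comparisons. For Mut_IDR3 against GFP 1489 (47.8%) of the 3114 genes were still called with the same sign, and for dIDR3 against GFP 3628 (84.5%) of the 4294. The shares were 71.5% for Mut_IDR3 against WT, 71.8% for dIDR3 against WT and 89.1% for Mut_IDR3 against dIDR3. The interferon-stimulated genes then had a median of 1.52, the NF-kB list 1.31, the AP-1 list 1.63 and the ZNF list -0.15 (adjusted p = 0.0421). Other lists called with WT moved by over 1.5 times. Hypoxia genes went from 0.31 to 0.10 (adjusted p = 0.0301), p53 targets from 0.43 to 0.18 (adjusted p = 0.000518), AP-2 targets from 0.35 to 0.18 (adjusted p = 0.0421), heat shock genes from 0.30 to 0.17 (adjusted p = 0.0164) and G1/S genes from -0.17 to -0.32 (adjusted p = 5.12e-06). With Mut_IDR3 against GFP, the AP-1 list went from 0.22 to 0.13, the AP-2 family from 0.14 to 0.07, heat shock genes from 0.16 to 0.05, hypoxia genes from 0.23 to 0.15, squamous differentiation from -0.17 to -0.30 and mitochondrially encoded mRNAs from -0.21 to -0.06, each still called, and YAP targets from 0.12 to 0.04, no longer called. With dIDR3 against GFP YAP targets went from 0.13 to 0.04, with Mut_IDR3 against WT AP-2 targets from -0.26 to -0.16, and between the mutants basal squamous genes from 0.15 to 0.10, each still called. The correction also added 6 list calls. They were ribosome biogenesis in WT against GFP (median -0.19, adjusted p = 8.5e-05), basal squamous genes in Mut_IDR3 against GFP (-0.11, adjusted p = 0.00148), Notch and Wnt genes (-0.19, adjusted p = 0.0175) and oxidative phosphorylation (-0.09, adjusted p = 0.0315) in dIDR3 against GFP, and mesenchymal genes (-0.08, adjusted p = 0.0436) and YAP targets (-0.03, adjusted p = 0.0467) in Mut_IDR3 against dIDR3.

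**Figure D2:**
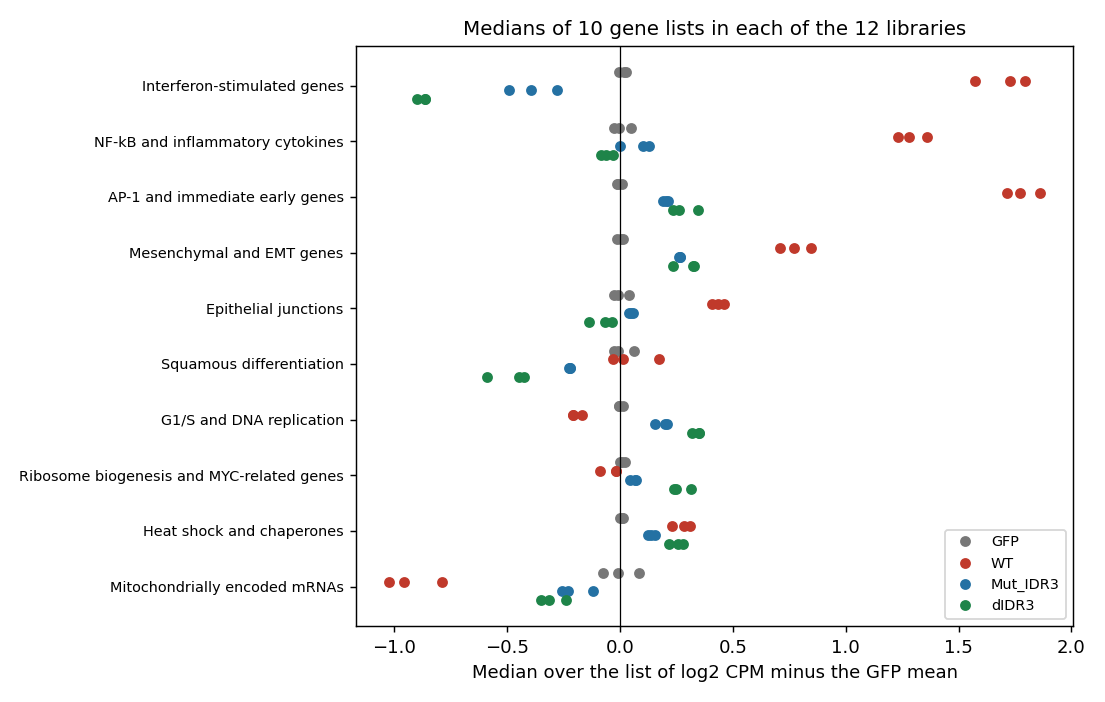
Median log2 level of 10 gene lists in each of the 12 libraries, relative to the mean of the GFP libraries, by group. Interferon-stimulated genes lay at 1.57 or higher in each WT library and at -0.28 or lower in each mutant library.

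Mut_IDR3 against GFP asks what the first altered form does on its own. Fewer genes changed than with WT, and some interferon-stimulated and squamous genes were among the falls. KRT14 fell 4.05-fold, from 227 ± 2.2 to 56.1 ± 2.65 CPM (log2 fold change -2.02, SE 0.06, adjusted p = 3.51e-11), where WT had raised it. IL1RN, which encodes an antagonist of interleukin-1, fell by 2.39 on the log2 scale (SE 0.24), and IFIT1 fell by 1.18. The inducible chaperone gene HSPA1A rose from 64 ± 3.02 to 129 ± 0.747 CPM (1.01, SE 0.06), with its reads uncertain against its near-identical copy HSPA1B.

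In all, 3114 genes (21.1%) differed between Mut_IDR3 and GFP, 1657 higher and 1457 lower, and 66 and 92 of them by at least 2-fold. The count was 1701 without GFP replicate 3 and 1566 without Mut_IDR3 replicate 2. ELMO3, a gene of cell migration, rose by 1.32, and DHRS2 and ARFGEF3 by 1.15 each. TENM2 rose by 1.03, ANO2 by 1.02, CTGF by 1.01 and ZDHHC14 by 0.97. PLLP rose by 1.28 (adjusted p = 0.0174), with adjusted p = 0.059 without GFP replicate 2, 0.06 without GFP replicate 3 and 0.111 without Mut_IDR3 replicate 3. RIMS2 fell by 1.89, MECOM by 1.69, GBP6 by 1.56, KLK8 by 1.48, TRIM22 by 1.37, DDX60 by 1.22 and KRT13 by 1.17 on the log2 scale. ZNF131 (-0.24, adjusted p = 0.0733, and 0.0398 with only these 2 groups in the fit), TFAP2A (-0.15, adjusted p = 0.105) and TFAP2C (0.15, adjusted p = 0.264) were not called. With the GC trend removed TFAP2A was called at -0.23 (adjusted p = 0.0152).

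With Mut_IDR3, 19 of 44 interferon-stimulated genes fell, such as IFIT3 (-1.03) and OAS1 (-0.97), 2 rose and 23 were not called, with 22 and 2 adjusted over the list alone and a median of -0.43 (adjusted p = 7.15e-06). Squamous differentiation genes fell in 11 of 34 cases, such as S100A9 (-1.07) and KLK5 (-0.43), 1 rose and 22 were not called, the same adjusted over the list alone. The median was -0.17, or -0.15 with groups at 0 set to their floor (adjusted p = 0.00276), and adjusted p = 0.0824 with an estimated correlation. It was -0.26 without GFP replicate 2, and -0.30 and -0.31 without Mut_IDR3 replicates 1 and 3. Genes of G1/S and DNA replication rose in 19 of 45 cases, such as MCM5 (0.52), MCM2 (0.46) and MCM3 (0.39), 3 fell and 23 were not called, with 23 and 4 adjusted over the list alone and a median of 0.20 (adjusted p = 4.99e-05). For G2/M genes 14 of 46 fell, such as BUB1 (-0.43), 5 rose, such as MYBL2 (0.58), and 27 were not called, with 23 and 6 adjusted over the list alone. Their median was -0.17 (adjusted p = 0.0212), and adjusted p = 0.333 with an estimated correlation and 0.0518 with the GC trend removed.

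Hypoxia and glycolysis genes rose with Mut_IDR3 in 17 of 36 cases, such as ALDOC (0.74) and DDIT4 (0.60), 2 fell and 17 were not called, the same adjusted over the list alone, with a median of 0.23 (adjusted p = 9.58e-06). Mesenchymal genes rose in 10 of 27 cases, such as TPM2 (0.72) and THBS1 (0.60), and 17 were not called, with 12 higher and 1 lower adjusted over the list alone and a median of 0.27 (adjusted p = 8.18e-05). AP-1 and immediate early genes rose in 13 of 34 cases, such as CYR61 (0.70, SE 0.04) and FOSL1 (0.59), and 21 were not called, with 14 and 1 adjusted over the list alone. Their median was 0.22 (adjusted p = 0.000129), and adjusted p = 0.0902 with an estimated correlation. The unfolded protein response list rose in 15 of 38 cases, such as HERPUD1 (0.66), 3 fell and 20 were not called, with 19 and 3 adjusted over the list alone and a median of 0.13 (adjusted p = 0.000154). Heat shock genes rose in 10 of 23 cases, such as HSPA8 (0.55), 2 fell and 11 were not called, with 11 and 3 adjusted over the list alone and a median of 0.16 (adjusted p = 0.00208).

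The remaining lists called for Mut_IDR3 lost their calls with an estimated correlation. AP-2 family members had 4 higher, TFAP2B itself and 3 more such as CITED2 (0.69), and 10 not called, with 5 adjusted over the list alone and a median of 0.14 (adjusted p = 0.0307). For this list adjusted p = 0.236 with an estimated correlation, and 0.0852 without Mut_IDR3 replicate 3. With TFAP2B left out of the list it was not called, at a median of 0.13 with 3 of 13 higher, or 4 adjusted over the list alone (adjusted p = 0.173). YAP and TEAD targets had 6 higher, 1 lower and 18 not called, the same adjusted over the list alone, with a median of 0.12 (adjusted p = 0.0245) and adjusted p = 0.414 with an estimated correlation. That call was also lost without GFP replicate 1 (0.0914), without Mut_IDR3 replicate 1 (0.0734) and with the GC trend removed (0.12), and the median was 0.06 without GFP replicate 3 and 0.08 without Mut_IDR3 replicate 1. Mitochondrially encoded mRNAs had 5 lower, such as MT-CO2 (-0.56), 1 higher and 7 not called, with 7 and 1 adjusted over the list alone. Their median was -0.21 (adjusted p = 0.00276), or -0.13 without GFP replicate 2, and adjusted p = 0.465 with an estimated correlation. ZNF genes had 52 lower, such as ZNF24 (-0.60), 16 higher and 299 not called, with 46 and 13 adjusted over the list alone and a median of -0.14 (adjusted p = 0.0044), and adjusted p = 0.285 with an estimated correlation. The NF-kB list, 3 higher, 5 lower such as CCL5 (adjusted p = 2.95e-05) and IL1B (-1.10), and 24 not called, or 6 and 6 adjusted over the list alone, had a median of 0.02 and a mean of -0.21 (adjusted p = 0.997).

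The second altered form, dIDR3, was compared with GFP in the same way. Some interferon-stimulated and squamous genes were among its falls, and some chaperone genes among its rises. HSPA8, a constitutive chaperone gene, rose from 1024 ± 39 to 2611 ± 63.8 CPM (log2 fold change 1.35, SE 0.06, adjusted p = 2.44e-09), and HSPA1A rose to 199 ± 5.6 CPM (1.64, SE 0.06). TENM2, a gene of cell adhesion, rose 4.43-fold from 12.3 ± 0.638 to 54.7 ± 4.17 CPM. KRT14 fell 4.87-fold to 46.6 ± 1.65 CPM (-2.29, SE 0.06), and IFITM3, which restricts viral entry, fell from 860.5 ± 43.8 to 492 ± 25.6 CPM (-0.81, SE 0.05).

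Between dIDR3 and GFP 4294 genes (29%) differed, 2309 higher and 1985 lower, and 136 and 307 of them by at least 2-fold. Of the calls 53.8% were higher, but 46.9% with upper-quartile scaling. MMP24 rose by a log2 fold change of 2.33, DNER by 2.11, MCAM by 1.95, HSPA2 by 1.74, CPED1 and ZNF703 by 1.71 each and DUSP4 by 1.59. GBP6 fell by 3.24, the acute-phase gene SAA1 by 3.07, KLK8 by 2.79, TRIM22 by 2.47, MUC16 by 2.35, LRG1 by 2.08, TRPV6 by 1.98 and KRT13 by 1.97 on the log2 scale. An ATXN7 entry (ENSG00000285258), which shares its symbol with another gene, fell by 3.56 (adjusted p = 0.015). Its adjusted p was 0.0507 without dIDR3 replicate 1, 0.0561 without dIDR3 replicate 2 and 0.154 by limma-voom. ZNF131 (-0.04, adjusted p = 0.801) and TFAP2C (0.20, adjusted p = 0.106) were not called. TFAP2A fell by 0.19 (adjusted p = 0.0376), with adjusted p of 0.0985, 0.0591 and 0.057 without GFP replicates 1, 2 and 3, and 0.0869 and 0.102 without dIDR3 replicates 2 and 3.

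With dIDR3, 32 of 44 interferon-stimulated genes fell, such as IFIT1 (-1.16), OASL (-1.08) and IRF1 (-0.72), and 12 were not called, with 36 lower and 1 higher adjusted over the list alone and a median of -0.99 (adjusted p = 1.93e-15). Squamous differentiation genes fell in 16 of 34 cases, such as NOTCH3 (-1.60), KLK5 (-0.74) and ZNF750 (-2.14), 3 rose and 15 were not called, with 21 and 3 adjusted over the list alone. Their median was -0.55, or -0.54 with groups at 0 set to their floor (adjusted p = 7.24e-07). Basal squamous genes fell in 11 of 27 cases, such as KRT15 (-1.38) and KRT17 (-0.79), 2 rose and 14 were not called, with 11 and 4 adjusted over the list alone and a median of -0.14 (adjusted p = 0.00951), and adjusted p = 0.426 with an estimated correlation. Genes of G1/S and DNA replication rose in 32 of 45 cases, such as RRM2 (0.80), UHRF1 (0.73) and FEN1 (0.66), 1 fell and 12 were not called, with 37 and 2 adjusted over the list alone and a median of 0.33 (adjusted p = 9.15e-13). Ribosome biogenesis genes rose in 27 of 46 cases, such as ODC1 (0.79) and NOP56 (0.58), 2 fell and 17 were not called, with 31 and 2 adjusted over the list alone and a median of 0.27 (adjusted p = 1.15e-07). Heat shock genes rose in 15 of 23 cases and 8 were not called, with 16 adjusted over the list alone and a median of 0.28 (adjusted p = 3.43e-07).

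AP-1 and immediate early genes rose with dIDR3 in 14 of 34 cases, such as FOSL1 (1.52), CYR61 (1.16) and JUN (1.13), and 20 were not called, with 15 adjusted over the list alone and a median of 0.29 (adjusted p = 2.22e-06). Mesenchymal genes rose in 13 of 27 cases, such as TPM2 (1.34), and 14 were not called, with 15 higher and 1 lower adjusted over the list alone and a median of 0.30 (adjusted p = 2.5e-05). YAP and TEAD targets had 8 higher, such as AXL (0.71), 1 lower and 16 not called, the same adjusted over the list alone, with a median of 0.13 (adjusted p = 0.00559), or 0.06 without dIDR3 replicate 2, and adjusted p = 0.321 with an estimated correlation. Hypoxia genes had 14 higher, such as ALDOC (1.05), 2 lower and 20 not called, with 19 and 2 adjusted over the list alone and a median of 0.19 (adjusted p = 0.000295), and adjusted p = 0.093 with an estimated correlation. Neural crest genes had 5 higher, such as SOX9 (0.73), 1 lower and 1 not called, the same adjusted over the list alone, with a median of 0.59 (adjusted p = 0.00611), and adjusted p = 0.0713 with an estimated correlation. Ribosomal protein genes had 12 lower, such as RPS3 (-0.26), 1 higher and 69 not called, with 11 lower adjusted over the list alone. Their median was -0.14 (adjusted p = 0.000351), with 0.141 by fry and adjusted p = 0.695 with an estimated correlation. Without dIDR3 replicate 2 it was -0.09 (adjusted p = 0.0477). Mitochondrially encoded mRNAs had 7 lower, such as MT-CO2 (-0.79), 1 higher and 5 not called, the same adjusted over the list alone, with a median of -0.26 (adjusted p = 0.00184), and adjusted p = 0.426 with an estimated correlation. The NF-kB list, with 7 higher, 9 lower such as SAA2 (-3.03), and 16 not called, or 8 and 9 adjusted over the list alone, had a median of -0.13 (adjusted p = 0.672).

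Mut_IDR3 against WT asks where the altered form differs from the unaltered protein. Both mutants also held more TFAP2B RNA than WT and changed genes against GFP. A difference from WT is thus not always an effect that was lost. Interferon and chemokine genes were among the lowest. CCL5 was at 0.716 ± 0.29 CPM with Mut_IDR3 against 846 ± 61.7 CPM with WT (log2 fold change -10.15, SE 0.14, adjusted p = 2.16e-16), and OASL was at 9.41 ± 1.31 against 1397 ± 32.7 CPM (-7.22, SE 0.09). SOX2, a transcription factor gene of squamous and stem cells, was at 8.12 ± 0.449 CPM with Mut_IDR3 and 0.105 ± 0.0431 CPM with WT (6.20, SE 0.36, adjusted p = 5.22e-09). KRT15 was 11.3-fold higher with Mut_IDR3 (3.50, SE 0.07), at 433 ± 11.1 CPM.

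Between Mut_IDR3 and WT 6519 genes (44.1%) differed, 3432 higher and 3087 lower with Mut_IDR3, and 414 and 558 of them by at least 2-fold. LOXL4 was 64.2-fold higher, CEL higher by a log2 fold change of 3.34, MYB by 3.01, IGFBP3 and TP73 by 2.74 each, GJA1 by 2.22 and ELF3 by 2.11. With no counts in the Mut_IDR3 libraries, IFNL1 was at least 1017-fold lower, IFNL3 at least 651-fold, CXorf49 at least 240-fold (239.9) and CCL3 at least 208-fold. IFNL2 was lower by a ratio of counts of 802 (222 to 6629) and SPOCK1 by 653 (180.4 to 5399). RSAD2 (-7.45), OAS2 (-7.44) and DHX58 (-7.36) were lower too.

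Of 44 interferon-stimulated genes, 38 were lower with Mut_IDR3 than with WT, 2 higher and 4 not called, the same adjusted over the list alone, and the median was -2.38 (adjusted p = 2.55e-20). The NF-kB list had 23 lower, such as TNFAIP3 (-3.30), 1 higher and 8 not called, the same adjusted over the list alone, with a median of -1.33 (adjusted p = 1.02e-11). AP-1 and immediate early genes had 29 lower, such as ZFP36 (3.99-fold), and 5 not called, with 30 adjusted over the list alone and a median of -1.45 (adjusted p = 2.46e-20). Mesenchymal genes had 16 lower, such as FN1 (-1.55), 3 higher and 8 not called, the same adjusted over the list alone, with a median of -0.53 (adjusted p = 4.4e-05). Targets of p53 had 16 lower, such as PMAIP1 (-2.65), 2 higher and 12 not called, with 16 and 4 adjusted over the list alone and a median of -0.33 (adjusted p = 0.000255). Histone genes had 15 lower, such as HIST1H1C (-1.47), and 18 not called, the same adjusted over the list alone, with a median of -0.78 (adjusted p = 2.83e-05). Genes of G1/S and DNA replication were higher in 37 of 45 cases, such as HELLS (1.35) and MCM6 (0.88), and 8 were not called, with 37 higher and 1 lower adjusted over the list alone and a median of 0.40 (adjusted p = 7.4e-11). Ribosome biogenesis genes had 27 higher, such as DDX18 (0.87), 4 lower and 15 not called, the same adjusted over the list alone, with a median of 0.23 (adjusted p = 0.00125).

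Several other lists called between Mut_IDR3 and WT were not called with an estimated correlation. Junction genes had 20 lower, such as CLDN4 (-1.98), 3 higher and 6 not called (median -0.40, adjusted p = 2.14e-06), and adjusted p = 0.0859 with an estimated correlation. Squamous differentiation genes had 18 lower, such as KLF4 (-2.70), 7 higher and 9 not called (median -0.32, adjusted p = 0.00716), and adjusted p = 0.0859 with an estimated correlation. AP-2 targets had 19 lower, such as GATA3 (-2.21) and KRT14 (-3.84), 9 higher and 5 not called (median -0.26, adjusted p = 0.0064), and adjusted p = 0.192 with an estimated correlation. The unfolded protein response list had 18 lower, such as XBP1 (-1.39), 5 higher and 15 not called (median -0.26, adjusted p = 0.00249), and adjusted p = 0.0678 with an estimated correlation. Neural crest genes had 5 lower, such as SOX9 (-1.89), 1 higher and 1 not called (median -0.38, adjusted p = 0.00793), and adjusted p = 0.0735 with an estimated correlation, and 0.119 when genes with low counts stayed in. Mitochondrially encoded mRNAs had 12 higher, such as MT-CYB (1.16), and 1 not called (median 0.52, adjusted p = 1.4e-05), and adjusted p = 0.242 with an estimated correlation. For all 6 of these lists the counts were the same adjusted over the list alone. Ribosomal protein genes had 29 lower, such as RPL13 (-0.49), 4 higher and 49 not called, with 28 and 4 adjusted over the list alone (median -0.15, adjusted p = 0.00112), and adjusted p = 0.66 with an estimated correlation, 0.0504 without WT replicate 2 and 0.0704 by fry. Oxidative phosphorylation genes had 26 lower, such as CYC1 (-0.31), 3 higher and 50 not called, the same adjusted over the list alone (median -0.14, or -0.21 without WT replicate 3, adjusted p = 0.00249), and adjusted p = 0.66 with an estimated correlation, 0.0504 without WT replicate 2 and 0.0867 by fry.

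For dIDR3 against WT the same question was asked of the second altered form. CCL5 was at 0.574 ± 0.14 CPM with dIDR3 (log2 fold change against WT -10.51, SE 0.14, adjusted p = 1.77e-16) and OASL at 6.94 ± 0.268 CPM (-7.65, SE 0.09). DHX58 had no counts with dIDR3 and was at least 999-fold lower. LOXL4 was 40.4-fold higher than with WT (5.34, SE 0.38), at 7.45 ± 0.708 CPM, and GJA1, a gap junction gene, was 5.6-fold higher, at 36.5 ± 2.01 against 6.51 ± 0.949 CPM.

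Between dIDR3 and WT 7730 genes (52.3%) differed, 4025 higher and 3705 lower with dIDR3, and 592 and 767 of them by at least 2-fold. JAM3 was higher by a log2 fold change of 2.50, NNT by 2.30, KRT15 and ACSS1 by 2.22 each, FKBP11 by 2.20 and NKX1-2 by 2.18. A second ATXN7 entry (ENSG00000163635) was higher by 2.25. With no counts in the dIDR3 libraries, IFNL1 was at least 1084-fold lower, IFNL3 at least 693-fold, IFNL2 at least 571-fold, CXorf49 at least 256-fold and CXCL10 at least 229.9-fold. RSAD2 (-8.89) and CFB (-8.09) were lower too.

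Of 44 interferon-stimulated genes, 41 were lower with dIDR3 than with WT, 1 higher and 2 not called, the same adjusted over the list alone, and the median was -3.01 (adjusted p = 7.5e-22). The NF-kB list had 25 lower, such as NFKBIA (-2.07), 1 higher and 6 not called, the same adjusted over the list alone, with a median of -1.32 (adjusted p = 6.7e-10). AP-1 and immediate early genes had 29 lower, such as ZFP36 (-2.09), 1 higher and 4 not called, with 30 and 1 adjusted over the list alone and a median of -1.26 (adjusted p = 2.79e-14). Squamous differentiation genes had 21 lower, such as KLF4 (-2.65), 2 higher and 11 not called, the same adjusted over the list alone, with a median of -0.62 (adjusted p = 1.19e-05). Targets of p53 had 16 lower, such as GADD45A (-1.56), 5 higher and 9 not called, with 16 and 6 adjusted over the list alone and a median of -0.28 (adjusted p = 0.00266). The unfolded protein response list had 25 lower, such as PPP1R15A (-2.15), 6 higher and 7 not called, with 26 and 6 adjusted over the list alone and a median of -0.29 (adjusted p = 4.63e-05). Histone genes had 13 lower, such as HIST1H1C (-1.71), and 20 not called, the same adjusted over the list alone, with a median of -1.10 (adjusted p = 2.09e-05). Genes of G1/S and DNA replication were higher in 41 of 45 cases, such as MCM10 (1.44) and MCM6 (1.14), and 4 were not called, the same adjusted over the list alone, with a median of 0.62 (adjusted p = 1.47e-13). Ribosome biogenesis genes had 30 higher, such as NCL (0.87), 2 lower and 14 not called, with 31 and 2 adjusted over the list alone and a median of 0.48 (adjusted p = 3.18e-07).

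Other lists called between dIDR3 and WT were not called with an estimated correlation. Junction genes had 21 lower, 4 higher and 4 not called, with 21 and 5 adjusted over the list alone (median -0.59, adjusted p = 2.43e-06), and adjusted p = 0.0902 with an estimated correlation. Mesenchymal genes had 13 lower, such as FN1 (-1.60), 5 higher and 9 not called, the same adjusted over the list alone (median -0.27, adjusted p = 0.00701), and adjusted p = 0.0902 with an estimated correlation and 0.063 with the GC trend removed. AP-2 targets had 18 lower, such as KRT14 (-4.11), 9 higher and 6 not called, the same adjusted over the list alone (median -0.43, adjusted p = 0.0145), and adjusted p = 0.238 with an estimated correlation and 0.0808 with the GC trend removed. Ribosomal protein genes had 47 lower, such as RPL13 (-0.65), 6 higher and 29 not called, with 49 and 6 adjusted over the list alone (median -0.30, adjusted p = 6.59e-06), and adjusted p = 0.552 with an estimated correlation. Oxidative phosphorylation genes had 39 lower, such as CYC1 (-0.46), 3 higher and 37 not called, with 40 and 3 adjusted over the list alone (median -0.24, adjusted p = 0.000121), and adjusted p = 0.552 with an estimated correlation. Mitochondrially encoded mRNAs had 10 higher, such as MT-CO3 (0.96), and 3 not called, the same adjusted over the list alone (median 0.26, adjusted p = 0.00218), and adjusted p = 0.452 with an estimated correlation and 0.0575 with the GC trend removed.

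Many genes that changed with WT differed from WT in the opposite direction in both mutants. Of the 8118 genes, 4913 (60.5%) were called in the opposite direction in both mutants against WT, 2375 that rose and 2538 that fell with WT. Of these, 4666 had a smaller change against GFP in both mutants than in WT. The genes were chosen for differing from WT in that direction, which by itself makes a smaller change likely. With a minimum of 2-fold in each comparison there were 570, of 1657 changed with WT. Independent lists would share 214 and 254, and the highest count in 20 simulations without any effect was 1. The values for independent lists do not allow for the WT libraries that the 3 comparisons share. The simulations share them but hold no real difference, so few genes are called in them. They cannot show how many genes a WT group that stands apart would give. When the GFP and mutant libraries were mixed and WT was kept, 2 splits gave 4023 and 4068, so much of the count can come from WT standing apart. Of genes with at least 5 CPM in the higher group, large rises were those of IFNL1, IFNL2, IFNL3, CXorf49, CCL5, RSAD2, CCL3, DHX58 and OASL. Large falls were those of LOXL4, KRT15, CEL, TP73, MECOM, NRIP1, KITLG (-2.27), BCHE (-2.26) and MAML2 (-2.14). KITLG, which encodes a growth factor, was at 16.8 ± 2.35 CPM with GFP, 3.48 ± 0.311 with WT, 10.5 ± 0.419 with Mut_IDR3 and 13.2 ± 2.87 with dIDR3. The change against GFP was smaller than with WT for 95.1% of the 8118 genes in Mut_IDR3, with a median ratio of 0.327, and for 90.8% in dIDR3, with a median ratio of 0.246. These genes were chosen in WT, which raises both shares. Of the 3114 genes called in Mut_IDR3, 33.7% changed less in WT, and of the 4294 called in dIDR3, 61.1% did.

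Some genes changed against GFP with all 3 constructs, 881 higher and 641 lower, and CITED2 was among the higher ones with 0.69 in Mut_IDR3 and 0.71 in dIDR3. Another 81 were higher with WT and lower with both mutants, such as KRT14 and CCL5, and 46 the reverse. WT and Mut_IDR3 shared 1264 higher and 1169 lower calls, where independent lists would share 460 and 396, and differed in sign in 179. WT and dIDR3 shared 1360 and 1042, where independent lists would share 640 and 539, and differed in 619. Mut_IDR3 and dIDR3 shared 1165 and 837, where independent lists would share 259 and 196, and differed in 16. The shared GFP libraries, too few to split, or the GC trend may give part of the excess. Shared calls were not recounted without that trend. In simulations without any effect at most 1 call was shared. Few genes are called there, so this bounds neither part. Across genes the log2 fold changes correlated with r = 0.37 for WT and Mut_IDR3, 0.31 for WT and dIDR3 and 0.59 for the mutants, beside 0.50, 0.50 and 0.50 in the simulations. The covariances were 0.229, 0.220 and 0.263, beside simulated values of 0.0636, 0.0634 and 0.0630.

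**Figure D3:**
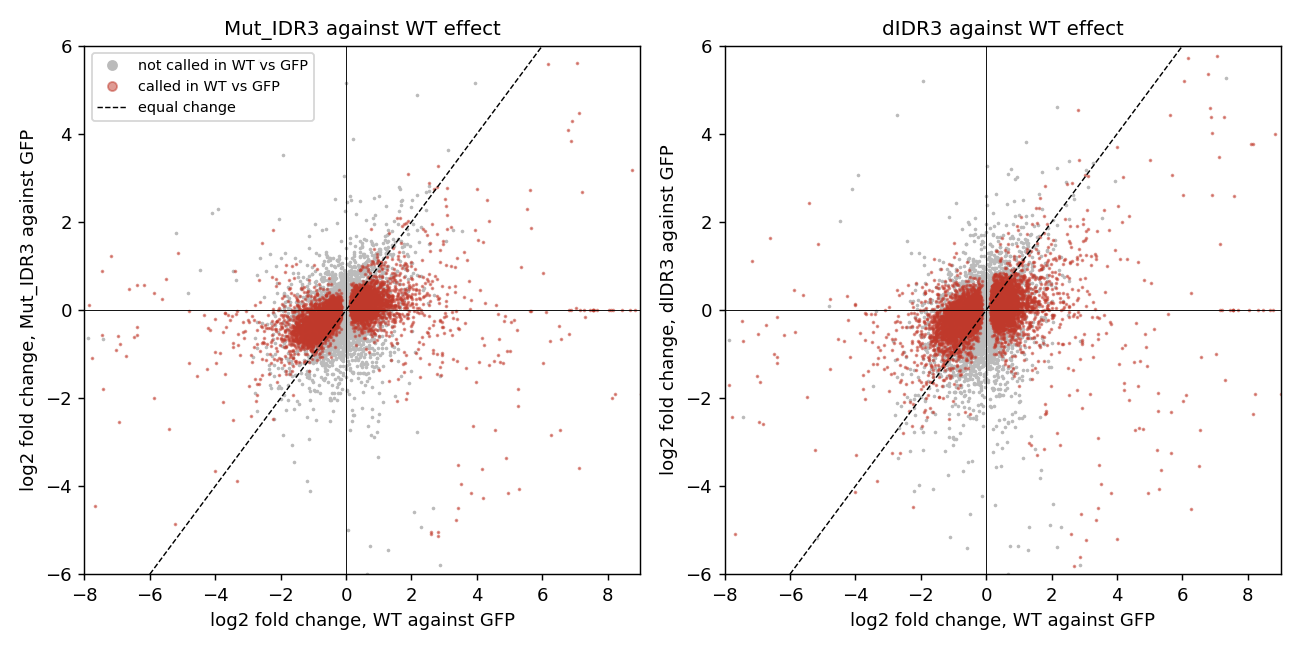
Log2 fold change against GFP with Mut_IDR3 and with dIDR3, plotted against that with WT, where each point is a gene and 40 and 43 genes lie outside the axes. The correlations across genes were 0.37 and 0.31.

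Mut_IDR3 against dIDR3 asks whether the 2 altered forms differ. SOX2 was higher in Mut_IDR3, at 8.12 ± 0.449 against 1.27 ± 0.554 CPM (log2 fold change 2.68, SE 0.27, adjusted p = 2.66e-05). KRT15 was 2.43-fold higher, at 433 ± 11.1 against 178 ± 14.1 CPM. MCAM, an adhesion molecule of melanoma and endothelial cells, was 4.61-fold lower (-2.21, SE 0.29, adjusted p = 0.000284), at 1.85 ± 0.463 against 8.59 ± 1.47 CPM. The chaperone gene HSPA8 was lower, at 1502 ± 35.6 against 2611 ± 63.8 CPM (log2 fold change -0.80, SE 0.06).

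In all, 1594 genes (10.8%) differed, 819 higher (51.4%) and 775 lower in Mut_IDR3, and with upper-quartile scaling 65.3% of the calls were higher. At least 2-fold changes were seen in 93 higher and 39 lower genes. The count was 917, 819 and 902 without Mut_IDR3 replicates 1, 2 and 3, and 844 and 948 without dIDR3 replicates 2 and 3. LRG1 was higher by 1.68, MUC16 by 1.56, TRPV6 by 1.53, CLIC3 and BCL6 by 1.14 each and SLPI by 1.12. ATXN7 (ENSG00000285258) was higher by 3.37 (adjusted p = 0.0432). Its adjusted p was 0.054, 0.154 and 0.0791 without Mut_IDR3 replicates 1, 2 and 3, 0.108 and 0.144 without dIDR3 replicates 1 and 2, 0.0833 by DESeq2 and 0.234 by limma-voom. VPS33B was higher by 1.18 (adjusted p = 0.0124), with adjusted p = 0.0671 without Mut_IDR3 replicate 2 and 0.0584 without dIDR3 replicate 2. RIMS2 (-1.69), EVI2A (-1.64), MMP24 (-1.53), ZNF703 (-1.16), DKK1 (-1.14), TENM2 (-1.12), ACSS1 (-1.08), MARCKSL1 (-1.05) and DUSP4 (-1.03) were lower in Mut_IDR3.

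Interferon-stimulated genes were higher in Mut_IDR3 than in dIDR3 in 20 of 44 cases, such as RSAD2 (1.44) and IFITM3 (0.69), and 24 were not called, with 27 adjusted over the list alone and a median of 0.48 (adjusted p = 1.42e-11). Squamous differentiation genes had 9 higher, such as NOTCH3 (1.04) and ELF3 (0.69), and 25 not called, with 12 higher and 1 lower adjusted over the list alone. Their median was 0.32, or 0.29 with groups at 0 set to their floor (adjusted p = 5.03e-05). Genes of G1/S and DNA replication had 18 lower, such as MCM10 (-0.55) and RRM2 (-0.46), and 27 not called, with 28 adjusted over the list alone and a median of -0.23 (adjusted p = 4.08e-10). Ribosome biogenesis genes had 21 lower, such as NOP56 (-0.52), and 25 not called, with 26 adjusted over the list alone and a median of -0.22 (adjusted p = 1.45e-11). Heat shock genes had 10 lower, such as HSPA8 (-0.80) and DNAJA1 (-0.63), and 13 not called, with 12 lower and 1 higher adjusted over the list alone and a median of -0.26 (adjusted p = 4.33e-07).

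The other lists called between the mutants were not called with an estimated correlation. Basal squamous genes had 9 higher, such as KRT17 (0.70), 6 lower and 12 not called, with 12 and 6 adjusted over the list alone (median 0.15, adjusted p = 0.0172), and adjusted p = 0.501 with an estimated correlation. Junction genes had 8 higher, such as CLDN7 (0.56), 1 lower and 20 not called, with 8 and 4 adjusted over the list alone (median 0.11, adjusted p = 0.000906), and adjusted p = 0.249 with an estimated correlation. Notch and Wnt genes had 9 higher, such as HES2 (0.88) and WNT10A (0.75), 2 lower and 12 not called, with 12 and 3 adjusted over the list alone (median 0.30, adjusted p = 0.000906), and adjusted p = 0.169 with an estimated correlation. The unfolded protein response list had 16 higher, such as CTH (0.52), 3 lower and 19 not called, the same adjusted over the list alone (median 0.17, adjusted p = 0.000906), and adjusted p = 0.0605 with an estimated correlation. G2/M genes had 6 lower and 40 not called, with 12 lower and 1 higher adjusted over the list alone (median -0.16, adjusted p = 0.00071), and adjusted p = 0.169 with an estimated correlation. AP-1 genes had 7 lower, such as FOSL1 (-0.92), 2 higher and 25 not called, with 8 and 2 adjusted over the list alone (median -0.08, adjusted p = 0.00659), and adjusted p = 0.232 with an estimated correlation and 0.0575 without dIDR3 replicate 1. That median was -0.05 and -0.12 without Mut_IDR3 replicates 1 and 2, and -0.05 without dIDR3 replicate 1. Ribosomal protein genes had 17 higher, such as RPLP1 (0.42), 1 lower and 64 not called, with 28 and 1 adjusted over the list alone (median 0.13, or 0.04 without dIDR3 replicate 2, adjusted p = 5.68e-06), and adjusted p = 0.609 with an estimated correlation and 0.191 by fry.

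Calls that rested on single libraries were seen between the mutants for 3 more lists. NRF2 and ferroptosis genes had 7 higher, such as FTH1 (0.31), 3 lower and 23 not called, with 8 and 3 adjusted over the list alone (median 0.12, adjusted p = 0.0268), and adjusted p = 0.0934 with an estimated correlation and 0.0562 without Mut_IDR3 replicate 1. Oxidative phosphorylation genes had 7 higher and 72 not called, the same adjusted over the list alone (median 0.09, adjusted p = 0.00215), and adjusted p = 0.666 with an estimated correlation, 0.338 without dIDR3 replicate 2 and 0.342 by fry. That median was 0.05 without Mut_IDR3 replicate 3 and 0.02 without dIDR3 replicate 2. Neural crest genes had 3 lower, such as SOX9 (-0.47), and 4 not called, with 4 lower and 1 higher adjusted over the list alone (median -0.39, adjusted p = 0.0219), and adjusted p = 0.142 with an estimated correlation and 0.0747 without dIDR3 replicate 1, and a median of -0.24 without dIDR3 replicate 3. The NF-kB list had 5 higher, such as SAA1 (1.93), 4 lower and 23 not called, with 7 and 6 adjusted over the list alone, and a median of 0.01 with a mean of -0.08 (adjusted p = 0.695).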

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

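The tests of the interferon pattern, of GC content and of the AP-1 genes were chosen after these patterns were seen, although the bounds of the GC tests with WT were set before the slopes and corrected values were computed, and the other splits of the libraries were chosen before.

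5 list results stood out because WT and a mutant were called in opposite directions against GFP, with a call in the direct comparison of that mutant with WT as well. Interferon-stimulated genes had medians of -2.38 for Mut_IDR3 against WT and -3.01 for dIDR3 against WT, from 1.76 with WT and -0.43 and -0.99 with the mutants against GFP. Genes of G1/S and DNA replication had medians of 0.40 for Mut_IDR3 against WT and 0.62 for dIDR3 against WT, from -0.17 with WT and 0.20 and 0.33 with the mutants. Ribosomal protein genes had a median of -0.30 for dIDR3 against WT, from 0.12 with WT and -0.14 with dIDR3, and their call was lost with an estimated correlation (adjusted p = 0.552, the highest of alternatives that began at 9.71e-09). The list was at 0.18, 0.20 and -0.04 in the 3 WT libraries and at -0.05, -0.27 and -0.08 in those of dIDR3, relative to the GFP mean. The call of WT against GFP was lost without WT replicate 2 (adjusted p = 0.208, in a range of 0.000565 to 0.751), and without dIDR3 replicate 2 the median of dIDR3 against GFP was -0.09. Beyond leaving each out, no test for single libraries that stand apart was made. Between replicates, chi-square per degree of freedom was 36.5 for WT replicates 2 and 3, 17.3 for 1 and 2, 18.1 for 1 and 3, and lower in the other groups. Which WT library differs is not settled by these values.

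The first pattern weighed is that interferon-stimulated genes were higher with WT and lower with both mutants than with GFP. More construct RNA in the WT libraries is argued against by TFAP2B, which was higher in both mutants than in WT. The smaller of the estimated log2 fold changes was 1.32, although the amount of protein was not measured here. A rise set off by any TFAP2B construct is argued against by the list medians of the mutants against GFP, the higher of which was -0.43. These medians are part of the pattern itself, so this is not a separate test. A response to GFP or to delivery could be present in the GFP cells too, so comparisons with GFP cannot show it. An antiviral response of the WT cultures that has nothing to do with the protein stays open, since each WT library lay at 1.57 or above and the labels give no separate culture or delivery that would part it from the construct. Within these limits, an effect of the unaltered protein that the altered forms lack is a candidate explanation and cannot be told apart from that response.

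Another pattern is that the changes between WT and GFP followed the GC content of the genes. Uneven bias in single libraries is argued against, because the lowest WT slope lay above the highest GFP slope by 0.232 log2 units per 10 GC points. GC-dependent bias as the whole cause of the changed genes is argued against by the 63.0% that were still called with the same sign after correction. That share includes NewGene features, 516 of the 8118 genes before correction, which had no GC value and were not corrected. For the lower ZNF genes it stays open, since the median of -0.15 after correction (adjusted p = 0.0421, in a range of 0.000118 to 0.226 over the alternatives) passed the bound set for it, but that bound left out the spread, with quartiles at -0.47 and 0.14. A part played by GC-dependent bias in the size of single changes, or a biological link of WT with GC-rich genes, may both hold and stay open.

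The last pattern is that AP-1 and immediate early genes were higher with all 3 constructs than with GFP. A consequence of the interferon response stays open for the rise with WT, because no value here goes against it. It stays open for Mut_IDR3 too, where the AP-1 median was 0.22 while the interferon list fell. That AP-1 call had adjusted p = 0.0902 with an estimated correlation, the highest of alternatives that began at 4.26e-05. With dIDR3 the interferon list fell (median -0.99, and adjusted p = 0.000254 with an estimated correlation, the highest of its alternatives). The AP-1 list rose there with a median of 0.29, and its highest adjusted p was 0.0465, also with an estimated correlation. The interferon and AP-1 lists thus moved in opposite directions with dIDR3, but this explanation stays open there as well. The bound set for both mutants was not met, since the quartiles of the AP-1 list span 0 after GC correction. GC-dependent bias is argued against for WT alone, by a median of 1.63 after correction. For the mutants it stays open, since the median after correction was 0.13 with Mut_IDR3 and 0.24 with dIDR3, from 0.22 and 0.29, with quartiles that span 0 in both, narrowly in dIDR3, although both stayed called (adjusted p = 0.00976 and 0.000146, where the dIDR3 alternatives ranged from 3.12e-07 to 0.0465). A response to any TFAP2B construct is a possible explanation that cannot be told apart from these, and handling that differed between the GFP cultures and the others was not tested.

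Other splits of the libraries were counted for each comparison. With 3 libraries against 3 there are 10 splits, so the share with as many genes is never under 0.1, and in each of the 6 comparisons 1 split, the real one, gave as many. The real count and the highest of the others were 8118 and 0 for WT against GFP, 3114 and 0 for Mut_IDR3 against GFP, and 4294 and 1 for dIDR3 against GFP. They were 6519 and 1 for Mut_IDR3 against WT, 7730 and 0 for dIDR3 against WT, and 1594 and 2 for Mut_IDR3 against dIDR3. For the genes changed with WT and opposite in both mutants against WT, 100 splits of the 12 libraries were drawn and 1, the real one, gave as many as 4913. The highest of the others gave 4068. That split and one with 4023 kept the 3 WT libraries together as the WT group. Another 4 that kept them together as a different group gave 0, and the 93 that parted them gave at most 24.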

How the results depend on the processing

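Removal of a GC or a length trend, the fits without mitochondrially encoded mRNAs upper-quartile scaling for the gene lists and the AP-2 family list without TFAP2B were chosen after seeing the data, and all other alternatives before.

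Most named genes were chosen for large changes or low adjusted p, so few of their calls were likely to be lost. The counts for them do not describe all called genes. With the GC trend removed, for example, 63.0% of all WT against GFP calls and 47.8% of those of Mut_IDR3 against GFP were kept. Of 734 results for named genes, DESeq2 and the stricter filter each ended 1 call, limma-voom 4, no low-count filter 7, median-ratio scaling 1 and upper-quartile scaling 3. A fit of only the 2 groups compared ended 3 calls and added 1. Removing the GC trend ended 25 calls and added 1. Leaving out single libraries changed 45 of the 734 results, with 146 of 4404 refits no longer past the threshold. ZNF131 in dIDR3 against GFP, not called at -0.04, was at 0.014 with the GC trend removed. TFAP2B in Mut_IDR3 against dIDR3, not called at -0.01, was at 0.00261 with median-ratio scaling, 0.00122 without a filter, 0.0026 by DESeq2 and 0.00372 with the GC trend removed. It was at 0.00793 with the stricter filter, 0.00521 with only the 2 groups in the fit and 0.0239 with upper-quartile scaling, and ranged from -0.069 to 0.0418 with single libraries left out. These values differ from 0 by less than their standard errors.

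The counts of changed genes stayed within 1.5 times of the reported ones under DESeq2, limma-voom, both other scalings, both other filters, the fits of 2 groups, the genes with symbols alone and the GC, length and mitochondrial alternatives. Across DESeq2, limma-voom and the scalings, WT against GFP ranged from 8078 to 8279 genes. A minimum change of 2-fold left 1657 genes for WT against GFP, 158 for Mut_IDR3 against GFP, 443 for dIDR3 against GFP, 972 for Mut_IDR3 against WT, 1359 for dIDR3 against WT, 132 for Mut_IDR3 against dIDR3, and 570 changed with WT and opposite in both mutants. An adjusted p under 0.01 left 1349 for Mut_IDR3 against GFP, 2506 for dIDR3 against GFP and 596 for Mut_IDR3 against dIDR3. These thresholds are stricter by construction. The share of WT genes with a smaller change was 98.0% in Mut_IDR3 and 95.9% in dIDR3 among genes changed at least 2-fold, and 97.0% and 93.3% at an adjusted p under 0.01. With the GC trend removed it was 88.9% in dIDR3, and the cause was not tested.

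With single libraries left out, the count ranged from 1566 to 2277 for Mut_IDR3 against GFP and from 819 to 1143 for Mut_IDR3 against dIDR3, where fewer samples enter the fit. The lowest counts came without Mut_IDR3 replicate 2 in both, and the highest without Mut_IDR3 replicate 1 and without dIDR3 replicate 1. It ranged from 7320 to 8329 for WT against GFP, 3099 to 3564 for dIDR3 against GFP, 5478 to 6772 for Mut_IDR3 against WT, 6792 to 7785 for dIDR3 against WT and 4084 to 5227 for genes changed with WT and opposite in both mutants. The shares with a smaller change ranged from 94.4% to 96.0% and from 90.4% to 92.4%. The correlations ranged from 0.31 to 0.47, 0.27 to 0.43 and 0.51 to 0.66.

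Of 180 list results, 89 were called, and 42 were called with an estimated correlation, which assumes less independence between genes. Of the 89, fry ended 6, removing the GC trend 5, no low-count filter 2, and the stricter filter, median-ratio scaling and upper-quartile scaling 0. With genes of low counts kept, medians moved by over 1.5 times for histones (0.45 in WT against GFP, -0.47 and -0.32 in Mut_IDR3 and dIDR3 against WT), neural crest genes (0.22 in WT against GFP, -0.03 in Mut_IDR3 against WT, -0.23 between the mutants) and p53 targets (-0.19 in Mut_IDR3 against WT). Leaving TFAP2B out of the AP-2 family list ended its call in Mut_IDR3 against GFP (adjusted p = 0.173). Leaving out single libraries ended 11 of the list calls at least once, and 84 to 93 lists were then called in all.

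Replicate numbers were also tried as a block. The block gave 7932 genes for WT against GFP, 2795 for Mut_IDR3 against GFP, 3984 for dIDR3 against GFP, 6280 for Mut_IDR3 against WT, 7471 for dIDR3 against WT, 1206 for Mut_IDR3 against dIDR3 and 4757 changed with WT and opposite in both mutants. The block shares were 95.3% and 91.1%, the correlations 0.36, 0.30 and 0.59, and 89 lists were called. It ended 8 of the 734 gene calls, and of the 89 list calls that of the AP-2 family in Mut_IDR3 against GFP (adjusted p = 0.0567). The numbers gave no sign of pairing the samples, although 3 libraries per group cannot exclude it and the labels do not explain them. Deviations from the group means correlated at -0.18 to 0.21 over the 18 same-numbered pairs (mean -0.01, 2 over 0.1) and at -0.14 to 0.25 over the 36 others (5 over 0.1).

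Depth limits the genes with few counts. A group with no counts allows a floor of 3 counts, so folds against it are lower bounds, as for IFNL1 with GFP.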

Other observations

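Transcripts of replication-dependent histone genes, most of which lack a poly(A) tail, took 0.0208 ± 0.000826% of counts with GFP, 0.0491 ± 0.00439% with WT, 0.0219 ± 0.000293% with Mut_IDR3 and 0.0205 ± 0.00134% with dIDR3. Ribosomal protein genes took 9.28 ± 0.0656%, 9.80 ± 0.521%, 9.20 ± 0.226% and 8.41 ± 0.461% in the same order. Features without an Ensembl identifier took 1.19 ± 0.0152%, 1.12 ± 0.0226%, 1.12 ± 0.0143% and 1.09 ± 0.0318%.

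The slope of gene level on GC content was -0.15 ± 0.03 log2 units per 10 GC points with GFP, 0.22 ± 0.09 with WT, 0.00 ± 0.04 with Mut_IDR3 and -0.07 ± 0.05 with dIDR3, relative to the mean of all libraries. Per doubling of transcript length the slope was 0.07 ± 0.01 with GFP, -0.14 ± 0.04 with WT, 0.01 ± 0.02 with Mut_IDR3 and 0.05 ± 0.04 with dIDR3. The first principal component held 37.6% of the variance and set the WT libraries apart, and the next held 13.5%.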
